A study of Mus musculus with 8 samples.

How the data were processed

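RNA was extracted from neural stem cells with a column kit, and sequencing libraries were made from total RNA after removal of ribosomal RNA with a strand-marking kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b. They give the mouse genome build under the names GRCm38 and mm10. Per the file headers, the authors' table gives a read count, an FPKM and a TPM for each gene and library. Filters and pooling are not given in the sources used here.

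Samples were grouped by their titles before the data were examined, and the tests were fixed then as well. The columns of the table were then matched to the samples by name alone. The main rule, chosen after seeing the column names, asked whether the whole code of a library stands in a sample's title, description, source name or characteristics. All 24 columns of values were left out, since 0 of them matched a sample. The tests that had been planned on the counts were therefore not run, and no depth, precision or self-test is reported.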

Results

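The series profiled gene expression in neural stem cells of the mouse subventricular zone, the germinal layer along the lateral ventricle. Cells came from control mice and from mice deficient in S1PR1, a G-protein-coupled receptor for the lipid sphingosine-1-phosphate. They were treated with high-density lipoprotein whose labels carry a minus or a plus sign for apolipoprotein M, the protein that carries sphingosine-1-phosphate on these particles. The 8 samples fall into 4 groups of 2: each of the 2 genotypes with each of the 2 lipoprotein preparations. The labels name the replicates by number and do not say whether they came from separate cultures or animals.

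The design implies the effect of the lipoprotein preparation within each genotype, the effect of the genotype under each preparation, and the difference between these effects. None of these comparisons was made here. The expression table names its libraries CH1, CH2, CV1, CV2, GH1, GH2, GV1 and GV2, and these 8 codes head 24 columns of values. No sample's labels hold any of the codes. As a first letter, C fits only the titles that begin with control, though it also stands inside the other titles. The letters H and V do not tell the preparations apart. In the titles, H stands in HDL, the lipoprotein abbreviation that both preparations share. V stands only in SVZ, the abbreviation of the tissue zone, which is in every title. The letter G begins no sample's title, so its genotype would follow only by elimination from reading C as control. A column was to be used only where its name gave a single sample or one of the 4 groups. The matching rules counted fits to single samples, and no separate rule sought a group. A code read for genotype alone gives neither a sample nor a group. The genotypes were therefore not compared over both preparations together either. The level of a gene was not used to assign the codes, so whether the level of S1pr1 could separate the genotypes was not tested. Assigning the codes to preparations by their order would have set the groups by a guess. The direction of every lipoprotein effect would have rested on that guess. Comparisons that need no such guess, such as H against V without a direction, were not made either. Because no column met the rule for use, no expression value, fold change or test is reported for any gene. Nothing is stated about how these cells responded to either preparation or differed with receptor deficiency.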

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

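Of the 24 columns, 0 fitted exactly one sample when the whole code was sought in the labels. This rule and 2 looser ones were all chosen after seeing the column names. With the first letter of the title and the replicate number, 0 columns fitted exactly one sample, and a column fitted between 0 and 2 samples. That rule does not read the letters H and V, so it could not separate the preparations within a genotype. With the letters of the code in order within the title and the replicate number, 0 columns fitted exactly one sample, and a column fitted between 0 and 4 samples. That rule reads H and V, but HDL and SVZ stand in every title, so it could not separate the preparations either. The same rule did not separate the genotypes, since C also stands in the word deficient. Each column with a C code fitted 4 samples. The counts of 0 under the looser rules thus follow from how those rules were built. They do not show whether the lack of a match depends on the rule. None of the alternatives planned for the tests of expression was run, because those tests had no mapped libraries. No paired analysis was possible because the columns could not be assigned to samples.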
